A study of Mus musculus with 12 samples.

How the data were processed

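The series holds 12 single-cell RNA sequencing libraries from mouse, 1 for each combination of tissue (brain cortex or whole spinal cord), genotype (wt or gp120) and age (2, 4 or 8 months). Per the labels' protocols, the tissue was digested with papain, triturated and strained, microglia were enriched in the bottom fraction of a density gradient, and tagmented cDNA libraries were sequenced on an Illumina HiSeq. The deposited tables hold raw UMI counts, a whole number for each gene and barcode, with 10000 barcodes per library. Reads were aligned with STAR 2.5 to the mm10 build, per the submitters' processing notes. The counting tool, the annotation and the rule by which barcodes were chosen are not given in the sources used here. How reads shared by near-identical genes or by overlapping genes on opposite strands or the same strand were counted is not given either. This leaves values of the H2 class I genes, Hspa1a and Hspa1b, Rnaset2b and Hba-a1 uncertain. It also leaves those of Ang and Rnase4 uncertain, which overlap on the same strand. The gp120 sequence itself was not analysed here. Gene positions come from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, in which 97.7% of the 25820 symbols were found, 1221 of them by an older symbol.

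A barcode was taken as a cell when it had at least 200 detected genes and at most 20% of its UMIs from mitochondrial genes. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed where the caller marked at least 0.5% of the cells, which left them in place in the 8-month wt cord library (1 of 4983 cells). Counts were log-normalised to 10000 UMIs per cell, and 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) gave clusters over all libraries together, with no batch correction. Clusters were named by a score on marker genes fixed before the data were examined, with a pseudocount of 5 CPM. A name needed 3 markers at a log2 difference of at least 1, and agreement with the 10 leading genes at 50 CPM or more. Mixed clusters were split again at resolution 0.5. Cells in clusters without a clear name, 8 to 72 per library, stayed unnamed. Class names end in "-like" because they rest on transcripts alone. Barcodes under 200 genes were summed per library as a measure of free RNA. What these barcodes hold was not tested. They held 52100 CPM of Hba-a1 in cortex and 63848 CPM in cord, so red blood cells or other cells with few genes may be among them.

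Raw counts were summed per library over the cells of a class, since cells of 1 library are not replicates. The microglia-like sums held 1547720 to 8426864 UMIs. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) at a Benjamini-Hochberg threshold of 0.05. Levels are CPM over the TMM-scaled library total, and the SE of a log2 fold change is its size over the square root of F. The model held tissue, genotype and age as factors (7 residual degrees of freedom). Genotype within a tissue and its difference between tissues came from a model with a tissue by genotype term (6 residual degrees of freedom). Other classes were tested where at least 3 libraries a side had 20 or more cells, which left out B cell, erythroid, fibroblast, monocyte and neutrophil classes, and the tissue comparison of neurons and oligodendrocyte precursors. A mean of 0 was set against a floor of 3 counts over the group's UMIs, which covers counting error only. The test was checked on simulated negative binomial counts, drawn around the mean share of each gene at its estimated dispersion, with 200 genes changed. Apart from library size and that dispersion, the simulated libraries did not differ. On these counts the test recovered 65.7% of 2-fold changes between tissues, 68.7% between genotypes and 58.2% between 8 and 2 months. It recovered 35.8% for genotype in cortex, 44.8% in cord and 10.4% for the tissue by genotype term.

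The genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean log2 CPM of at least 5 and the same direction in every matched pair, and leaves out mitochondrial, ribosomal protein and unnamed genes. Where no gene passed, the 5 with the smallest p were taken. Another 13 genes were named whatever their result (P2ry12, Tmem119, Cx3cr1, Apoe, Cst7, Il1b, Ccl3, Ccl4, Tnf, H2-D1, Ifitm3, Fos and Mbp). Members of the gene lists were added as examples. A few genes that the rule names are not reported here. There were 22 gene lists fixed before the data were examined and 16 marker lists of cell classes. They were tested in the microglia-like sums with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. List members were also adjusted over the list alone. Shares of cells were compared over matched pairs with an exact two-sided sign-flip permutation test.

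The alternatives tried were DESeq2 1.42.0, limma voom, DESeq2 size factors in edgeR, no expression filter, a mean of at least 10 CPM, and age as a number or matched pairs as a block. Cells were also chosen by a minimum of 500 genes, by at most 10% mitochondrial UMIs, with doublets kept, with equal cells per library, over all cells whatever their class, or by a marker gate of at least 3 microglia UMIs and at most 1 UMI of any other class. Each library was left out in turn. Shares were recomputed at Leiden resolution 0.5 and with cells thinned to 300 UMIs. Chosen after seeing the data were male cells alone in the library of both sexes, leaving out the 8-month wt cord and 4-month gp120 cortex libraries together, leaving out cluster 14, keeping clusters 11, 18 and 19 alone, and leaving out each library in the other classes. The scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.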

Results

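Single-cell RNA sequencing was performed on mouse brain cortex and whole spinal cord at 2, 4 and 8 months of age. The mice were either wild type (wt) or carried the genotype label gp120, the name of the envelope glycoprotein of HIV. The study asked how cell transcriptomes compared between these genotypes and tissues over the 3 ages, and its title concerns the heterogeneity of microglia, the resident macrophages of the brain and spinal cord. Each of the 12 combinations of tissue, genotype and age was 1 library. The 4 groups therefore held 3 libraries each, 1 per age, and the microglia-like cells were compared over matched libraries. Of the rarer classes, 5 were compared over 6 to 11 libraries, such as T or NK cell-like sums over 4 wt and 6 gp120 libraries. Nothing in the labels says that the libraries came from separate animals, so the spread between these libraries may be technical. With 1 library per combination, the p-values take their error from the residual of the model. That residual mixes library-to-library variation with the interactions that a model leaves out. Each library held 10000 barcodes, and the libraries held 6102620 to 12138736 unique molecular identifiers (UMIs). After filtering, 3170 to 8886 cells per library remained, with a median of 598 to 1254 UMIs per cell. Of the microglia-like cells of the 4-month gp120 cortex library, 2344 had UMIs of Xist or Tsix (female) and no Y-linked UMI, and 612 had Y-linked UMIs (male) and neither Xist nor Tsix. The other 11 libraries had at most 3 microglia-like cells with Xist or Tsix.

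Microglia-like cells were the largest class in 11 of 12 libraries, in suspensions that had been enriched for microglia on a density gradient. Their share was 39.0% ± 9.10 (SD, n = 3) in wt cortex, 68.4% ± 9.45 in gp120 cortex, 41.5% ± 9.15 in wt cord and 58.4% ± 3.1 in gp120 cord. It was higher in gp120 compared to wt in 6 of 6 matched pairs, as was the share of T or NK cell-like cells, which averaged 0.529% ± 0.360 (n = 6) in wt and 1.91% ± 0.976 in gp120. The shares of endothelial-like, ependymal-like, oligodendrocyte-like, neuron-like and neutrophil-like cells were lower in gp120 in 6 of 6 pairs. The neutrophil-like class held only 0 to 12 cells per library, and in cord at 4 months 3 in wt and 5 in gp120. Shares within a library are not independent, since a higher microglia-like share leaves less for the other classes together. These falls therefore do not show a loss of cells. Cord libraries held more endothelial-like cells (14.3% ± 2.46 against 1.84% ± 1.06, n = 6), ependymal-like cells (8.21% ± 3.36 against 0.742% ± 0.367) and oligodendrocyte-like cells (10.5% ± 5.54 against 2.90% ± 1.80) than cortex libraries in 6 of 6 pairs. Cortex libraries held more pericyte or smooth muscle-like cells (27.9% ± 14 against 4.07% ± 1.39) and neuron-like cells (3.80% ± 3.65 against 0.177% ± 0.119) in 6 of 6 pairs. Astrocyte-like cells made up 9.63% ± 3.66 (n = 3) of wt cortex, 0.80% ± 0.903 of gp120 cortex, 0.702% ± 0.554 of wt cord and 1.11% ± 0.039 of gp120 cord. With 6 pairs the exact two-sided sign-flip permutation test cannot give a p below 0.03125, which each of these 6-of-6 differences reached. Its Benjamini-Hochberg adjusted value over the 15 classes was 0.0670, so no share passed the correction.

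**Figure D1:**
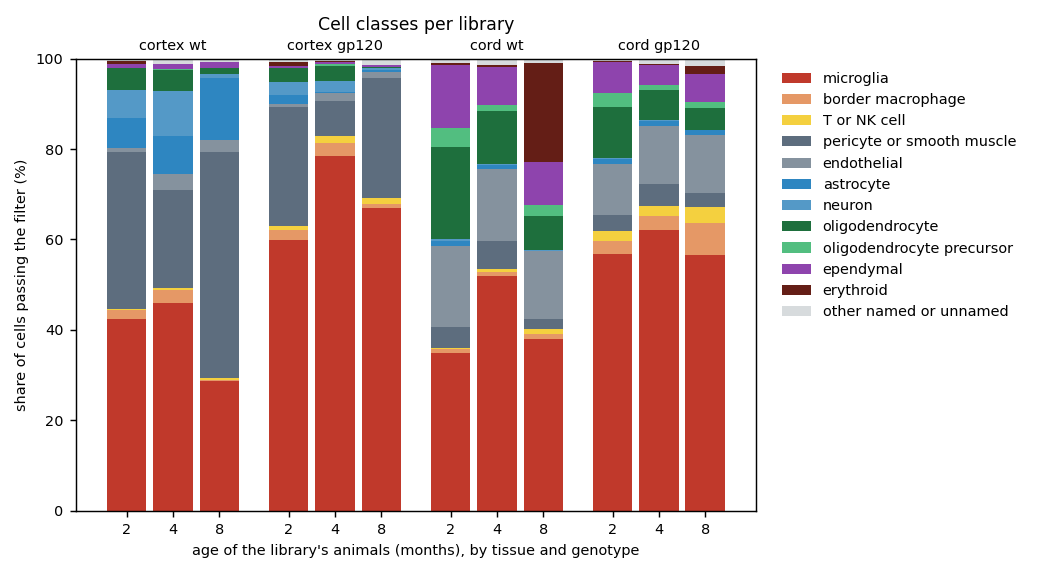
Share of cells passing the filter (vertical axis, %) in each cell class, 1 bar per library, ordered by tissue, genotype and age in months (horizontal axis). The microglia-like share is taller in gp120 than in wt at each age of each tissue, and the 8-month wt cord library holds 22.0% erythroid-like cells.

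Microglia-like cells of the spinal cord were compared with those of the cortex over all 12 libraries. Transcripts of inflammatory mediators and of early response transcription factors were higher in cord. Tnf, a proinflammatory cytokine (GRCm38 chromosome 17, 35199381 to 35202007), averaged 23.6 ± 11.2 CPM (SD, n = 6 libraries) in cortex and 612 CPM in cord, a log2 fold change of 4.72 (SE 0.20, adjusted p = 5.91e-09). Il1b, the interleukin 1 beta gene (chromosome 2, 129364570 to 129371139), was higher by 4.30 (SE 0.61, adjusted p = 0.000255), and the chemokine genes Ccl3 and Ccl4 by 3.79 (SE 0.15) and 4.11 (SE 0.21). The largest rise was that of Adamts1, a secreted metalloprotease (chromosome 16, 85793827 to 85803113), from 23.1 ± 9.89 to 787 ± 289 CPM (log2 fold change 5.13, SE 0.17, adjusted p = 1.85e-09). It was followed by the transcription factors Fosb (5.06, SE 0.37) and Klf2 (4.93, SE 0.23), and by Tnfsf9, Cxcl2, Ccrl2, Atf3, Dusp2, Il12b, Ptgs2 and Maff with log2 fold changes of 4.39 to 4.89. Fos was higher by 3.50 (SE 0.31, adjusted p = 4.77e-06). Among genes that define resting microglia, P2ry12 was lower in cord by a log2 fold change of -0.57 (SE 0.17, adjusted p = 0.0290, 5 of 6 pairs), whereas Tmem119 (-0.28, adjusted p = 0.157) and Cx3cr1 (-0.01, adjusted p = 0.962) did not pass the test. Apoe (1.07, adjusted p = 0.403) did not pass either.

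The largest falls in cord were those of contractile genes of smooth muscle. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), averaged 523 ± 416 CPM in cortex and 26.4 CPM in cord (log2 fold change -4.02, SE 0.40, adjusted p = 1.18e-05), and Tagln, Myh11, Tpm2, Myl9, Mylk, Cald1 and Tpm1 fell by -3.93 to -2.54 on the log2 scale. In barcodes with fewer than 200 genes, taken here as a measure of free RNA, Acta2 stood at 2164 CPM in cortex and 106 CPM in cord. It was also lower in the T or NK cell-like cells of cord (-3.52, SE 0.459). Outside the contractile genes, Mgp (-2.08), the B cell adaptor Bank1 (-1.72), D4Wsu53e (-1.61, SE 0.09, adjusted p = 9.36e-08) and Mfge8 (-1.54), which bridges dying cells to phagocytes, were lower in cord. The free RNA held 373 CPM of Mgp and 316 CPM of Mfge8 in cortex and 111 and 47.1 CPM in cord. The class I gene H2-D1 was higher by 1.01 (adjusted p = 0.00374), Ifitm3 by 0.67 (adjusted p = 0.0390) and the myelin gene Mbp by 1.52 (adjusted p = 0.0117). The free RNA held 332 CPM of Mbp in cortex and 1482 CPM in cord. In all, 2773 of 11107 genes passed the test, 1570 higher and 1203 lower in cord. The 2 tissues filled different clusters of the microglia-like class: the largest cluster was 11 or 19, led by homeostatic genes, in 5 of 6 cortex libraries and 17 or 7, led by Ccl4, Il1b and Tnf, in 6 of 6 cord libraries. In cells of clusters 11, 18 and 19 alone, chosen after seeing the data, 1183 genes passed.

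**Figure D2:**
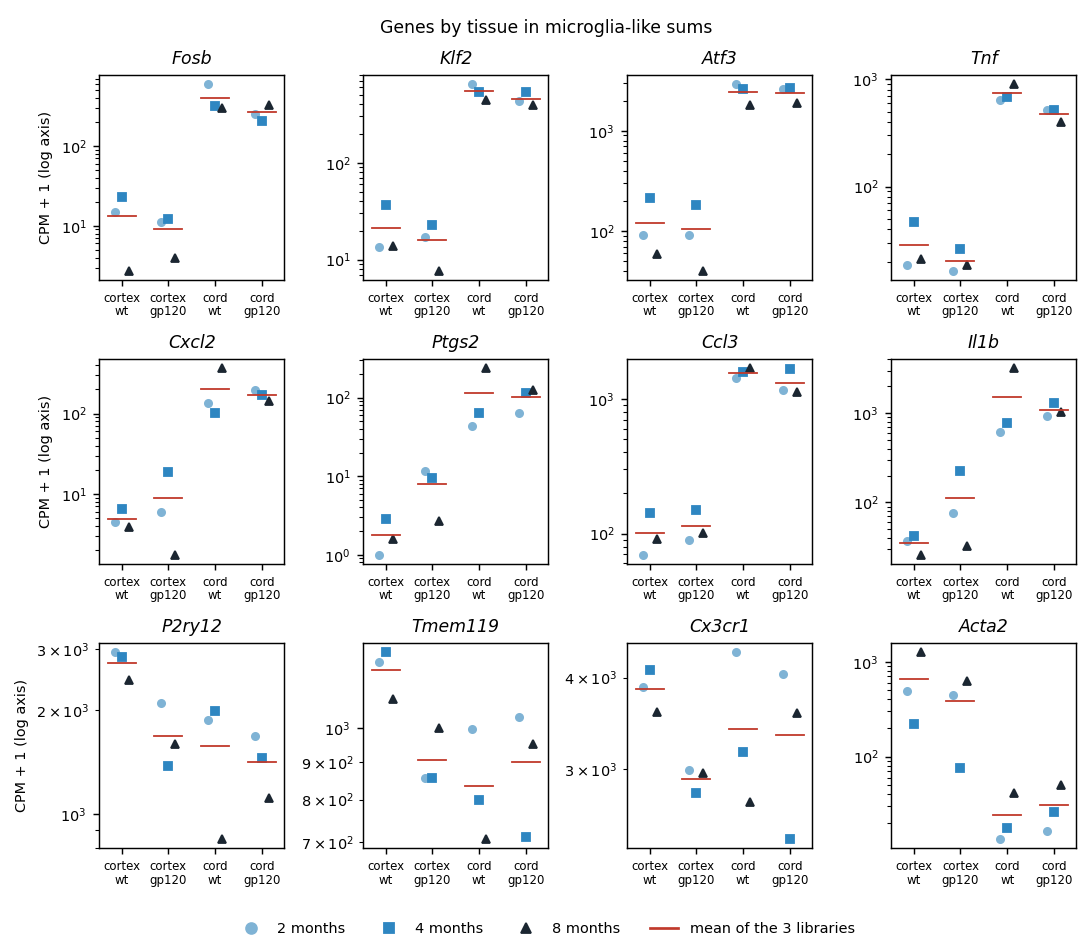
CPM + 1 (vertical axis, log scale) of 12 genes in the microglia-like sum of each library (points, shaped by age in months) by tissue and genotype (horizontal axis), with red lines at the mean of the 3 libraries of a group. The 6 cord libraries lie above the 6 cortex libraries for Fosb, Klf2, Atf3, Tnf, Cxcl2, Ptgs2, Ccl3 and Il1b and below them for Acta2.

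Of the gene lists fixed before the data were examined, members of the immediate early and dissociation stress list were higher in cord. Of its 23 measured members 21 rose, also when adjusted over the list alone (camera with a preset correlation, adjusted p = 8.68e-30, and adjusted p = 0.0777 with an estimated correlation). All 18 measured members of the NF-kB response list rose, again 18 when adjusted over the list alone (adjusted p = 2.66e-21, and 0.0777 with an estimated correlation). Nfkbiz was higher by 4.19 (SE 0.24), Nfkbia by 3.44 (SE 0.14) and Tnfaip3 by 3.31 (SE 0.11). Of 20 cytokine and chemokine genes 17 rose, or 18 with 1 that fell when adjusted over the list alone (adjusted p = 2.87e-15, and 0.0875 with an estimated correlation). Of 16 cholesterol biosynthesis genes 10 rose, 11 when adjusted over the list alone (adjusted p = 6.75e-06, and 0.205 with an estimated correlation), among them Insig1, a regulator of sterol synthesis (2.34, SE 0.24). Ribosomal protein genes had a median log2 fold change of 0.54, and 23 of 34 rose, 33 when adjusted over the list alone (adjusted p = 1.25e-11, and 0.379 with an estimated correlation). The type I interferon list did not pass (5 of 22 rose, 4 when adjusted over the list alone, adjusted p = 0.384), nor did the disease-associated microglia list (3 of 24 rose, 1 when adjusted over the list alone, adjusted p = 0.255). Of 21 homeostatic microglia genes, Jun (2.66, SE 0.17) and Txnip rose and Fcrls (-1.01, SE 0.15), Crybb1, Sall1 and P2ry12 fell, the same numbers when adjusted over the list alone (adjusted p = 0.197). Markers of other cell types moved with tissue in the same sums. Endothelial markers rose (9 of 11, 10 when adjusted over the list alone, adjusted p = 2.42e-07, and 0.205 with an estimated correlation), as did oligodendrocyte markers (7 of 11, 8 when adjusted over the list alone, adjusted p = 0.00190, and 0.660 with an estimated correlation). Pericyte or smooth muscle markers fell (7 of 8, also when adjusted over the list alone, adjusted p = 6.75e-06, and 0.379 with an estimated correlation).

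Microglia-like cells of gp120 mice were compared with those of wt mice over both tissues. Interferon-stimulated genes and a few genes that were almost silent in wt were higher in gp120. Qpct, glutaminyl-peptide cyclotransferase (chromosome 17, 79051906 to 79090378), averaged 2.88 ± 2.12 CPM in wt cortex, 86.0 ± 22.7 in gp120 cortex, 6.76 ± 3.82 in wt cord and 140 ± 83.7 in gp120 cord (n = 3 each), a log2 fold change of 4.49 (SE 0.26, adjusted p = 2.16e-06). Ccr6, a chemokine receptor (chromosome 17, 8236043 to 8257141), was higher by 6.02 (SE 0.79, adjusted p = 0.00182), and Msh5, a meiotic recombination gene (chromosome 17, 35028605 to 35046745), by 3.89 (SE 0.57, adjusted p = 0.00355). The 2-month gp120 cord library held 0.78 CPM of Ccr6 and 5.18 CPM of Msh5, against 0.48 and 4.35 CPM in the matched wt library, while the other 5 gp120 libraries held 50.6 to 88.6 and 43.0 to 92.7 CPM. The B cell chemoattractant Cxcl13 was higher by 3.16 (SE 0.59, adjusted p = 0.0152) and the monocyte chemoattractant Ccl12 by 1.58 (adjusted p = 0.0436). The interferon-induced genes Ifi27l2a (2.51, SE 0.39), Ifi204 (1.91), Ifitm3 (1.55, SE 0.22, adjusted p = 0.00309) and Ifit2 (1.54) rose, as did Fcgr4, a receptor for immunoglobulin G (1.95), Niacr1 (1.71) and Fgl2 (1.65, SE 0.20). Ifitm3 averaged 43.9 ± 24.9 CPM in wt cortex, 171 ± 77.1 in gp120 cortex, 103 ± 82.2 in wt cord and 197 ± 60.2 in gp120 cord.

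Falls in gp120 were smaller. Rnaset2b (chromosome 17, 6970634 to 7011299) fell by -1.33 on the log2 scale (SE 0.29, adjusted p = 0.0371), the ribonuclease gene Ang by -1.24 (SE 0.15, adjusted p = 0.00128), the phosphatase gene Dusp7 by -1.24 (SE 0.16) and the chromatin protein gene Hmgb1 by -0.92 (SE 0.12, adjusted p = 0.00182). Fam102b, Meg3, Odc1, Lsp1, Atp2c1, Mgll, Hist3h2a and Arrdc3 fell by -0.92 to -0.70. Meg3 is a neuron marker, and the share of neuron-like cells was lower in gp120. In cortex Meg3 stood at 621 CPM in wt and 567 CPM in gp120 free RNA, against 37.6 and 16.6 CPM in microglia-like cells. For Mgll the free RNA of cortex held 131 and 53.2 CPM, and the microglia-like cells 100 and 43.4 CPM. H2-D1 was higher by 0.93 (SE 0.21, adjusted p = 0.0421, 5 of 6 pairs). P2ry12 (-0.41, adjusted p = 0.301), Apoe (1.30, SE 0.90, adjusted p = 0.559), Cst7 (1.63, adjusted p = 0.473) and Tnf (-0.59, adjusted p = 0.138) did not pass the test. In all, 201 of 11107 genes passed, 113 higher and 88 lower in gp120. With limma voom 220 genes passed and 44.5% of them were higher, against 56.2% with edgeR. The count was 512 without the 8-month wt cord library, and 116, 114, 101 and 109 without the 2-, 4- or 8-month wt cortex library or the 8-month gp120 cortex library.

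By list, 14 of 22 type I interferon genes rose in gp120, 21 when adjusted over the list alone, with a median log2 fold change of 1.42 (adjusted p = 4.19e-24, and 0.60 with an estimated correlation). Rtp4 was higher by 1.40 (SE 0.16) and Oasl2 by 1.94 (SE 0.33). Of 17 antigen presentation genes 4 rose, 9 when adjusted over the list alone (adjusted p = 2.11e-06, and 0.768 with an estimated correlation). They were H2-K1 (1.34, SE 0.205), Nlrc5 (1.46, SE 0.30), Psmb9 (0.65, SE 0.14) and H2-D1. No ribosomal protein gene passed over all genes, and 19 of 34 rose and 1 fell when adjusted over the list alone (adjusted p = 8.59e-13, and 0.768 with an estimated correlation). No member of the homeostatic microglia list or the disease-associated list passed, over all genes or over the list alone. The camera test ranked the first list lower (adjusted p = 0.000295, median log2 fold change -0.22) and the second higher (adjusted p = 0.0497, median 0.43) in gp120 than other genes, with 0.768 and 0.779 for an estimated correlation.

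Microglia-like cells of gp120 and wt mice were then compared within the cortex. Genes of lipid-handling, disease-associated microglia were higher in gp120 cortex. Cluster 20, led by Gpnmb, Spp1 and Cst7, held 1.21%, 1.67% and 1.5% of the microglia-like cells of wt cortex at 2, 4 and 8 months and 3.82%, 21.2% and 8.56% of those of gp120 cortex. Cluster 21, led by Xist, held 29.0% of those of the 4-month gp120 cortex library, which stood apart from the other cortex libraries with 18294 CPM of Apoe and 477 CPM of Cst7. Without this library and the 8-month wt cord library, chosen after seeing the data, 312 genes passed. Gpnmb, a transmembrane glycoprotein of phagocytes (chromosome 6, 49036546 to 49070929), had 0 UMIs in the 3 wt cortex libraries and averaged 278 ± 238 CPM (n = 3) in gp120 cortex, which was at least 628-fold higher than a floor of 3 counts over the wt group (adjusted p = 0.0180). Spp1, osteopontin (chromosome 5, 104435118 to 104441050), rose from 19.9 ± 23.5 to 670 ± 123 CPM (log2 fold change 5.95, SE 1.11, adjusted p = 0.0104), Cst7, a cathepsin inhibitor, from 14.1 ± 5.0 to 248 ± 204 (4.08, SE 0.78, adjusted p = 0.0119) and Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188), from 998 ± 345 to 9616 ± 7607 (3.26, SE 0.78, adjusted p = 0.0351). The complement gene C4b (6.35), Ccr6 (5.94), Igf1 (5.27), Cxcl13 (4.97), Qpct (4.81), Msh5 (4.26), Fabp5 (4.03), H2-Aa (3.76) and Wfdc17 (3.56) rose too, as did Ifitm3 (2.01, SE 0.26) and H2-D1 (1.42). Genes of astrocytes led the falls: Aldoc (chromosome 11, 78322968 to 78327781) averaged 65.5 ± 27 CPM in wt and 7.98 ± 6.83 in gp120 cortex (-3.17, SE 0.38, adjusted p = 0.000887), followed by Clu (-2.36). The free RNA of these libraries held 433 CPM of Aldoc in wt and 33.0 CPM in gp120 cortex, beside the lower share of astrocyte-like cells given above. Lrba, Ang, Dusp7, Mgll, Lsp1, Meg3, Cd164, Sox4 and Fam102b fell by -1.41 to -1.10. P2ry12 (-0.70, adjusted p = 0.0920), Tmem119 (-0.40, adjusted p = 0.221) and Cx3cr1 (-0.41, adjusted p = 0.273) did not pass.

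Cluster 14, led by Ccl12, Cxcl13 and Ifi204, held 1.31%, 4.15% and 3.82% of the microglia-like cells of wt cortex at 2, 4 and 8 months and 5.32%, 15.8% and 23.7% of those of gp120 cortex. Of 23 type I interferon genes 21 rose in gp120 cortex, 23 when adjusted over the list alone (adjusted p = 2.00e-26, and 0.216 with an estimated correlation). Cluster 16, led by Top2a and Mki67, held 3.78%, 2.11% and 1.13% of the microglia-like cells of wt cortex at 2, 4 and 8 months and 8.05%, 5.25% and 7.73% of those of gp120 cortex. Of 22 cell cycle genes 13 rose, 19 when adjusted over the list alone (adjusted p = 1.21e-15, and 0.216 with an estimated correlation), with Mki67, a marker of dividing cells, at 10.7 ± 6.07 CPM in wt and 105 ± 9.20 in gp120 cortex. Of 24 disease-associated microglia genes 10 rose, 14 when adjusted over the list alone (adjusted p = 2.61e-08, and 0.602 with an estimated correlation), and 6 of 17 antigen presentation genes, 10 when adjusted over the list alone (adjusted p = 4.14e-08, and 0.448 with an estimated correlation). Of 21 homeostatic microglia genes 2 fell, P2ry13 (-0.84, SE 0.19) and Gpr34 (-0.79, SE 0.19), and 9 fell when adjusted over the list alone (adjusted p = 2.15e-07, and 0.448 with an estimated correlation). Of 10 astrocyte markers 7 fell and 1, Gfap (3.49, SE 0.53), rose, with 8 and 1 when adjusted over the list alone (adjusted p = 3.94e-07, and 0.448 with an estimated correlation). Whether reads of the gp120 transgene add to the count of Gfap is not known from the labels. In all, 491 of 11513 genes passed, 295 higher and 196 lower. With limma voom 516 passed and 47.3% of them were higher, against 60.1% with edgeR. The count was 749 without the 8-month wt cord library, and 194, 130, 159 and 198 without the 2-, 4- or 8-month wt cortex library or the 4-month gp120 cortex library.

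**Figure D3:**
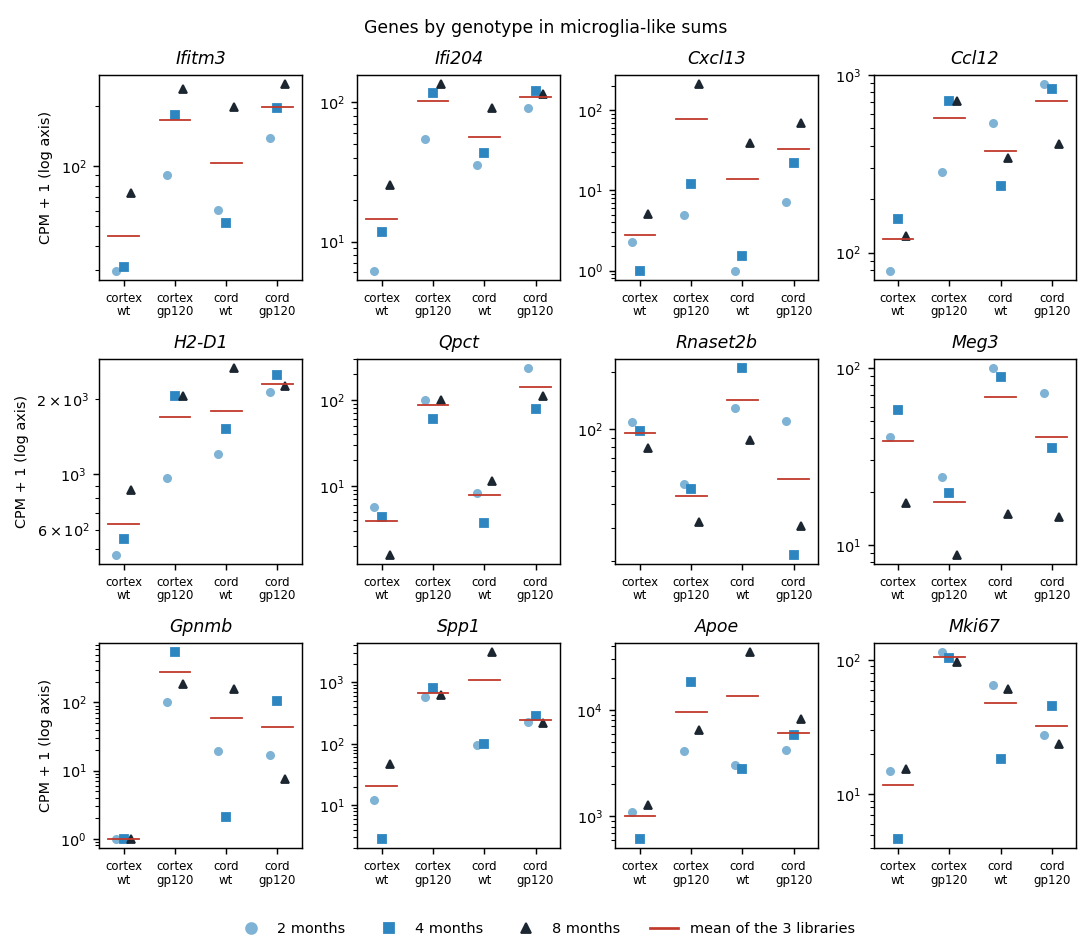
CPM + 1 (vertical axis, log scale) of 12 genes in the microglia-like sum of each library (points, shaped by age in months) by tissue and genotype (horizontal axis), with red lines at the mean of the 3 libraries of a group. Qpct lies higher in the 6 gp120 libraries than in the 6 wt libraries, and Gpnmb, Spp1 and Mki67 are higher in gp120 than in wt cortex libraries, while the wt cord libraries overlap those of gp120 cord.

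Within the spinal cord, 9 of 11513 genes passed, each higher in gp120, while of 64 genes with DESeq2 57.8% were higher. Of these, 3 met the naming rule: Qpct (4.29, SE 0.35, adjusted p = 9.75e-05), the nuclear body gene Sp100 (chromosome 1, 85649988 to 85709998; 1.10, SE 0.17, adjusted p = 0.0368) and the leukocyte gene Lst1 (chromosome 17, 35185095 to 35188439; 1.10, SE 0.17, adjusted p = 0.0368). Ifitm3 (1.12, adjusted p = 0.125), Apoe (-0.66, adjusted p = 0.952) and Cst7 (-0.55) did not pass. Apoe was higher in gp120 cord at 2 months (3026 CPM in wt and 4161 in gp120) and 4 months (2759 and 5755) and lower at 8 months (35109 and 8244), and Cst7 likewise (22.7 and 47.7, 39.1 and 97.2, 325 and 50). No interferon gene passed over all genes and 13 of 23 rose when adjusted over the list alone (median 0.96, adjusted p = 4.56e-15, and 0.650 with an estimated correlation). The count was 5 without the 2-month wt cord library and 5 without the 8-month wt cortex library. It was 16 without the 2-month gp120 cord library, and 23, 27 and 18 without the 2-, 4- or 8-month gp120 cortex library.

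The difference between the 2 tissues in the gp120 effect was tested as an interaction, and 27 of 11513 genes passed, 2 with a more positive and 25 with a more negative effect in cord. Genes of dividing cells made up most of those named. The effect on Mki67 (chromosome 7, 135689784 to 135716361) was lower in cord than in cortex by a log2 difference of -3.88 (SE 0.62, adjusted p = 0.0285), that on Top2a by -3.24 (adjusted p = 0.0285) and that on Cenpe by -3.27 (adjusted p = 0.0399). Mki67 averaged 47.2 ± 26.0 CPM in wt and 31.3 ± 11.7 in gp120 cord. Hmgb2, Incenp, Ezh2, Slfn2 and Bcl2a1d had differences of -2.68 to -1.53, and Aldoc one of 3.21 (adjusted p = 0.0285). Apoe (-3.91, adjusted p = 0.217) and Cst7 (-4.63, adjusted p = 0.113) did not pass. Of 22 cell cycle genes 6 had a lower effect in cord, 18 when adjusted over the list alone (adjusted p = 5.05e-25, and 0.0763 with an estimated correlation), and none of 24 disease-associated genes, 14 when adjusted over the list alone (adjusted p = 3.19e-15, and 0.483 with an estimated correlation). All 24 measured members of the latter list were higher in the 8-month wt cord library than on average (mean log2) over the other 5 cord libraries. Spp1 stood at 93.8 CPM in wt and 227 in gp120 cord at 2 months, 98.2 and 279 at 4 months, and 3132 and 213 at 8 months. Across the 11513 genes, which are not independent replicates, the cortex and cord effects of gp120 had a Pearson correlation of 0.221 and a Spearman correlation of 0.164. Limma voom called 0 genes for this interaction and DESeq2 99. The count was 0 without the 8-month wt cortex library, 2 to 7 without any of 6 others (2- or 4-month wt cortex, 4-month gp120 cortex, 2-month wt cord, 2- or 8-month gp120 cord), 45 without the 8-month gp120 cortex library and 74 without the 4-month wt cord library.

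**Figure D4:**
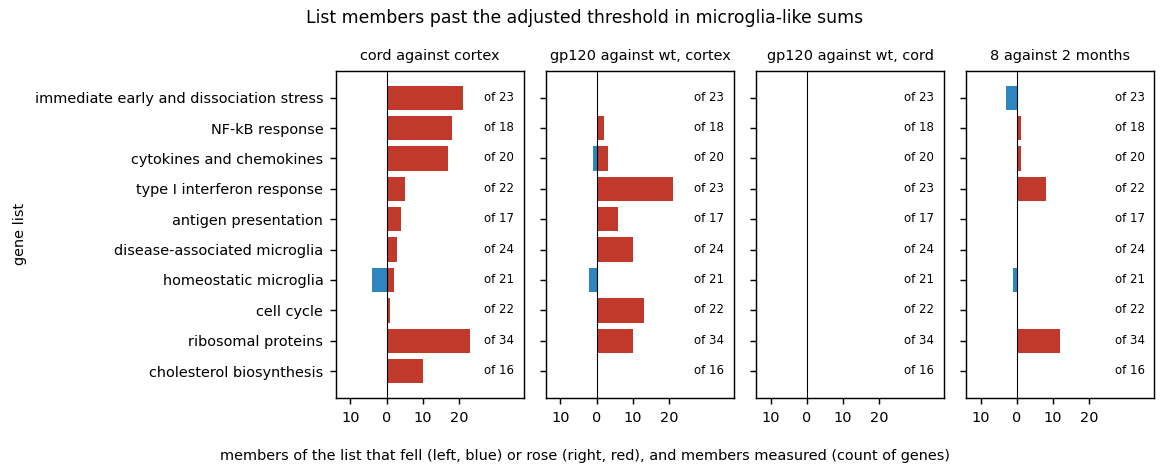
Members of 10 gene lists (vertical axis) that rose (red, to the right) or fell (blue, to the left) in microglia-like sums, as a count of genes (horizontal axis), with the number measured beside each bar, for cord against cortex, gp120 against wt in each tissue and 8 against 2 months. The immediate early list reaches 21 of 23 members in the tissue panel and the interferon list 21 of 23 in the cortex panel, while no bar appears for gp120 in cord.

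Age was compared over both tissues and genotypes. The labels used here name no preparation batch, so age cannot be told apart from a batch shared by the libraries of an age. At 8 compared to 2 months, interferon-induced genes were higher. The median mitochondrial share of UMIs per cell was 11.8% and 12.2% in wt and gp120 cortex and 7.33% and 8.38% in wt and gp120 cord at 2 months, and 7.55%, 5.25%, 6.82% and 5.0% at 8 months. In cortex, the largest microglia-like cluster was 19 at 2 months (72.3% in wt and 58.9% in gp120) and 11 at 8 months (85.3% and 48.2%). Cxcl13 (chromosome 5, 95956951 to 95961068) was higher by 4.99 (SE 0.70, adjusted p = 0.00302), the T cell chemoattractant Ccl5 by 2.36, Ifi27l2a by 1.92 (adjusted p = 0.0459), the checkpoint ligand gene Cd274 by 1.46, Ifit2 by 1.45 and Ifitm3 by 1.41 (SE 0.27, adjusted p = 0.0151). Bcl2a1d (2.40), Ly6a (2.10), Ly6c1 (2.00), Ildr2 (1.72), Mgp (1.59) and Naalad2 (1.51) rose too. The free RNA of cortex and cord held 112 and 276 CPM of Ly6a, 143 and 445 of Ly6c1, and 373 and 111 of Mgp. The microglia-like cells held less, 27.1 and 65.9, 19.6 and 78.4, and 72.45 and 18.1 CPM. For Bcl2a1d, Ildr2 and Naalad2 they held more than the free RNA in both tissues. The non-coding RNA Meg3 (chromosome 12, 109541001 to 109571726) fell by -2.07 (SE 0.28, adjusted p = 0.00260). It stood at 594 CPM in the free RNA and 27.1 CPM in the microglia-like cells of cortex, where the share of neuron-like cells was 6.00% in wt and 3.05% in gp120 at 2 months and 0.845% and 0.371% at 8 months. The immediate early transcription factors Egr1 and Jun fell by -1.42 (SE 0.29, adjusted p = 0.0225) and -0.97 (adjusted p = 0.0225), and Hist1h1e, Arsb, Adamts1, Ralgps2, Pibf1, Btg2, Dmxl1, Fer and Fchsd2 by -1.23 to -0.78. The chemokine genes Ccl3 (0.19, adjusted p = 0.623) and Ccl4 (-0.06, adjusted p = 0.943), Apoe (2.14, SE 0.95, adjusted p = 0.280), Cst7 (2.33, adjusted p = 0.260) and Fos (-1.12, adjusted p = 0.120) did not pass. In all, 271 of 11107 genes passed, 203 higher and 68 lower at 8 months. The count was 149 in cells with at most 10% mitochondrial UMIs and 67 with a gate on marker genes, which left 6546 genes to test. It was 117 without the 2-month wt cord, 70 without the 2-month gp120 cord, 102 without the 2-month wt cortex, 142 without the 8-month wt cortex, 180 without the 8-month gp120 cortex and 409 without the 4-month gp120 cortex library.

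Of 22 interferon genes 8 rose at 8 compared to 2 months, 21 when adjusted over the list alone (median 1.34, adjusted p = 1.41e-16, and 0.311 with an estimated correlation). Of 34 ribosomal protein genes 12 rose, 25 when adjusted over the list alone (adjusted p = 1.31e-21, and 0.311 with an estimated correlation). Of 23 immediate early genes 3 fell, Btg2, Jun and Egr1, with 8 lower and 1 higher when adjusted over the list alone (adjusted p = 1.64e-05, and 0.385 with an estimated correlation). Endothelial markers moved with age in the same sums, 7 of 11 higher and 11 when adjusted over the list alone (adjusted p = 6.06e-10, and 0.311 with an estimated correlation). Between 2 and 4 months edgeR called 0 genes, with 1055 at an unadjusted p under 0.05, DESeq2 called 74 and limma voom 23. Among genes at a mean log2 CPM of at least 5 that the naming rule admits, Atp6v1g1 (0.59, adjusted p = 0.126) and the proto-oncogene Myc (0.98, adjusted p = 0.126) had the smallest p. Between 4 and 8 months edgeR called 0 genes, with 1397 at an unadjusted p under 0.05, DESeq2 called 171 and limma voom 160. Hist1h1e (-1.53, adjusted p = 0.0551), Meg3 (-1.78, adjusted p = 0.0551) and Cxcl13 (3.56, adjusted p = 0.0566) came closest among the genes that the rule admits.

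The tissue difference changed with age for 18 genes in an interaction test. Cebpb, a transcription factor of myeloid cells, was higher in cord than in cortex by 1.36 at 2, 2.57 at 4 and 4.84 at 8 months (adjusted p = 0.00884), and Fos by 3.30, 2.51 and 4.79 (adjusted p = 0.0106). The myelin gene Cldn11 differed by -0.10, 0.48 and 3.12 (adjusted p = 0.00884) and the haemoglobin gene Hba-a1 by -1.77, 2.30 and 4.96 (adjusted p = 0.0443), and 22.0% of the cells of the 8-month wt cord library were erythroid-like. The heat shock genes Hspa1b (0.96, -1.67 and 2.83) and Hspa1a (1.15, -1.35 and 2.64) were higher in cord at 2 and 8 months and lower at 4 months (adjusted p = 0.0443). No gene passed for an age-dependent genotype effect with edgeR, with 429 at an unadjusted p under 0.05, and limma voom called 0 and DESeq2 10. Among genes at a mean log2 CPM of at least 5, the smallest p was that of the splicing factor gene Cwc22 (chromosome 2, 77881159 to 77946375), whose gp120 effect was 4.05 at 2, 3.13 at 4 and 0.27 at 8 months (adjusted p = 0.0706). Without the 8-month gp120 cord library 123 genes passed for tissue by age. Without the 8-month wt or gp120 cortex library none did, and without the 2-month wt cortex, 2-month gp120 cortex, 4-month gp120 cortex, 2-month gp120 cord or 4-month gp120 cord library 5, 4, 9, 7 and 7 did.

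The same comparisons were run in the other classes with at least 20 cells in 3 or more libraries a side. Between tissues, 2333 genes passed in oligodendrocyte-like, 1476 in pericyte or smooth muscle-like, 1279 in ependymal-like, 1200 in endothelial-like, 264 in astrocyte-like, 156 in border macrophage-like and 29 in T or NK cell-like sums. The border macrophage count was 88, 100 and 102 without the 4-month gp120 cord, 2-month gp120 cortex or 4-month gp120 cortex library, and the T or NK cell count was 7, 14, 10 and 5 without the 2-, 4- or 8-month gp120 cord or the 8-month gp120 cortex library. Some of the homeobox genes named by the rule had UMIs in cord alone or in cortex alone, while homeobox genes as a group were not tested. Hoxa7, a homeobox gene of the posterior body axis (chromosome 6, 52214491 to 52221854), had 0 UMIs in cortex and averaged 284 ± 31.6 CPM (n = 6) in ependymal-like cells and 154 ± 105 CPM (n = 5) in astrocyte-like cells of cord, at least 58.7-fold and 62.7-fold higher than a floor of 3 counts over the cortex libraries. Hoxb7 in endothelial-like cells of cord averaged 87.3 ± 11.8 CPM against 0 UMIs in cortex (at least 47.0-fold higher). Lhx2, a forebrain homeobox gene (chromosome 2, 38339281 to 38369733), averaged 434 ± 118 CPM in astrocyte-like cells of cortex and had 0 UMIs in those of cord (at least 30.0-fold lower). Immediate early genes rose in cord in 20 of 22 members in endothelial-like, 19 of 22 in oligodendrocyte-like, 16 of 20 in ependymal-like, 16 of 21 in border macrophage-like, 14 of 22 in pericyte or smooth muscle-like and 6 of 18 in T or NK cell-like sums, and 21, 19, 17, 19, 17 and 14 rose when adjusted over the list alone, with 1 that fell in border macrophage-like sums. Fos was higher in cord by 4.69 (SE 0.23) in endothelial-like and 5.27 (SE 0.42) in oligodendrocyte-like cells. Wound and matrix remodelling genes fell in endothelial-like (10 of 14), ependymal-like (10 of 14) and pericyte or smooth muscle-like sums (10 of 13), and in 12, 11 and 10 when adjusted over the list alone. The pericyte channel genes Abcc9 (3.49, SE 0.25) and Kcnj8 (2.94, SE 0.27) were higher in cord pericyte or smooth muscle-like sums. That class does not part pericytes from smooth muscle cells, and whether their mix differed between the tissues was not tested. The granzyme gene Gzmb (2.76, SE 0.51) and the activation marker Cd69 (2.17, SE 0.31) were higher in T or NK cell-like cells of cord. The chemokine gene Ccl8 was lower in cord border macrophage-like cells (-4.06, SE 0.35).

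Between genotypes, the other classes gave fewer calls: 175 in pericyte or smooth muscle-like, 59 in oligodendrocyte-like, 56 in neuron-like, 46 in border macrophage-like, 38 in endothelial-like, 26 in ependymal-like, 15 in astrocyte-like, 10 in oligodendrocyte precursor-like and 4 in T or NK cell-like sums. Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), was higher in gp120 astrocyte-like cells, from 65.1 ± 80.9 to 4921 ± 2039 CPM (n = 5; log2 fold change 7.15, SE 0.37, adjusted p = 2.88e-21), and in ependymal-like cells, from 37.6 ± 34.8 to 545 ± 538 CPM (n = 6; 3.85, SE 0.28, adjusted p = 2.51e-10). The labels do not say whether the gp120 transgene holds Gfap sequence, whose reads would be counted as Gfap. C4b was higher in gp120 astrocyte-like (2.61, SE 0.61, adjusted p = 0.0132) and oligodendrocyte-like cells (2.55, SE 0.51, adjusted p = 0.0216), and the prostaglandin dehydrogenase Hpgd in oligodendrocyte-like cells (3.84, SE 0.58, adjusted p = 0.00173). Border macrophage-like cells of gp120 mice had more Ccl8 (3.17, SE 0.38, adjusted p = 1.63e-05), Ccl5 (5.08, SE 1.26) and H2-Aa (1.28, SE 0.22) and less of the scavenger receptor Cd36 (-1.58, SE 0.22) and of Pf4 (-0.92, SE 0.18). The free RNA held 29.1 CPM of Ccl5 in wt and 103 CPM in gp120, and 44.0 and 159 CPM of H2-Aa. Interferon genes rose in gp120 in 4 of 10 measured members in oligodendrocyte-like and 5 of 9 in pericyte or smooth muscle-like sums, each 7 when adjusted over the list alone, and in 2 of 4 in neuron-like sums. None passed of 20 in border macrophage-like, 21 in endothelial-like, 6 in ependymal-like and 6 in T or NK cell-like sums, where 0, 1 with 1 that fell, 1 and 0 rose when adjusted over the list alone. In pericyte or smooth muscle-like sums 9 of 18 homeostatic microglia genes, and in neuron-like sums 7 of 18, also rose in gp120, where the share of microglia-like cells was higher. In astrocyte-like sums 11 of 11 were higher in gp120 (median log2 1.11), of which 2 passed, 5 when adjusted over the list alone. In oligodendrocyte-like sums 1 of 20 homeostatic microglia genes rose, with 10 higher and 1 lower when adjusted over the list alone. With 1 library left out, these counts ranged from 45 to 285 (pericyte or smooth muscle), 33 to 180 (oligodendrocyte), 9 to 158 (neuron), 21 to 39 (border macrophage), 21 to 98 (endothelial), 17 to 40 (ependymal), 4 to 25 (astrocyte), 7 to 16 (oligodendrocyte precursor) and 0 to 7 (T or NK cell).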

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

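The tests of pseudogenes, of sex with male cells alone, of a single wrong label and of a swap of labels, and the genes Gm6472, Gfap and mt-Nd3 there, were chosen after the results were seen. A library stood apart from the other 5 of its tissue in 14 of the 68 groups of 6 libraries that were tested on 34 measures. Chance gives about 1 in 20 for values drawn from 1 normal distribution. The 6 libraries mix genotypes and ages, and some measures move together, so the 14 cannot be set against that rate.

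The 8-month wt cord library stood apart from the other cord libraries with a median of 598 UMIs and 354 genes per cell, 22.0% erythroid-like and 0.080% astrocyte-like cells, and 35109 CPM of Apoe, 325 CPM of Cst7 and 3215 CPM of Il1b in microglia-like cells. The 4-month gp120 cortex library stood apart with 18294 CPM of Apoe, 477 CPM of Cst7 and 225 CPM of Il1b. The 4-month wt cortex library stood apart with 0.312% monocyte-like cells and 45.5 CPM of Tnf. The 8-month wt cortex library stood apart with a median of 668 genes per cell, and the 8-month gp120 cord library with 7.19% border macrophage-like cells.

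The effect of genotype differed between the tissues for 27 genes and that of age for 18 genes, each by an interaction test. The log2 differences between the cord and the cortex effect of gp120 were 3.21 for Aldoc, -3.88 for Mki67, -3.27 for Cenpe, -3.24 for Top2a, -2.68 for Bcl2a1d, -1.79 for Slfn2, -1.74 for Ezh2, -1.60 for Incenp and -1.53 for Hmgb2. For tissue by age the adjusted p was 0.00884 for Cebpb and Cldn11, 0.0106 for Fos, 0.0317 for Ccr6, and 0.0443 for Nr4a1, Dnajb1, Hba-a1, Rgs5, Ier2, Hspa1b, Hspa1a and Ppp1r10.

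Immediate early and NF-kB genes were higher in cord microglia-like cells, with a median log2 change of 2.87 over 41 genes. Microglia-like cells held more of these transcripts than barcodes under 200 genes, by a median log2 ratio of 2.23 over the 6 cord libraries. The ratio was more than 1 in 5 of them, and was lowest at 8 months (1.14 in wt and 0.744 in gp120 cord). This argues against free RNA in the cord suspension as the whole source only as far as these barcodes stand for free RNA. RNA of red blood cells among them would raise the ratio. Stress of the preparation acting on every cell of the cord suspension cannot be told apart from a difference between the tissues, because each tissue was prepared as its own suspension. The median change of both lists in endothelial-like and pericyte-like sums was 0.392 of that in microglia-like sums, while the immediate early list alone had medians of 2.48 in endothelial-, 2.61 in oligodendrocyte-, 2.65 in ependymal- and 0.779 in pericyte-like against 2.96 in microglia-like sums, and the NF-kB list 0.742, 0.578, 1.85 and 1.10 against 2.38. A difference between cord and cortex microglia in the animal stays open and was not tested.

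Of the 201 genes that passed between genotypes, 178 had the same direction in 6 of 6 pairs. Sex of the animals is argued against as the source for most of these 178 genes. With the library of both sexes reduced to male cells 82.6% still passed with the same direction, a share that this choice of genes favours. The same direction in the pairs without that library is no test, since these genes were chosen for it. None of this covers the other genes that passed. A strain variant or other inherited difference carried by all cells cannot be told apart from the gp120 genotype itself for most of these genes, although the 2-month gp120 cord library stood near wt for Ccr6 (0.78 CPM against 0.48 in 2-month wt cord) and Msh5 (5.18 against 4.35). Of 53 such genes abundant enough in pericyte-like sums, 75.5% kept their direction there, of which 10 passed the test, and free RNA of microglia may add to that share. Reads shared between paralogs or pseudogenes stay open too, since 3.9% of these genes are annotated pseudogenes but no value shows reads shared between coding paralogs, and an effect of gp120 stays open.

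The 8-month wt cord library had more of the disease-associated list than the mean log2 of the other 5 cord libraries, with all 24 measured genes higher and a median log2 ratio of 1.59 in microglia-like cells. In its endothelial-like cells 23 of 23 were higher, with a median of 1.90. The microglia-like excess over endothelial-like cells was therefore -0.313. Free RNA or blood in the suspension predicts such a value, but so does RNA of microglia reaching the endothelial-like cells. The value therefore does not decide whether free RNA was the source. Cluster 20, led by Gpnmb, Spp1 and Cst7, held 9.06% of the microglia-like cells of this library, against 0.68% to 2.4% in the other cord libraries. A swap of labels with the 8-month gp120 cord library is argued against, since 0 of 10 genes that separate the genotypes lay on the wt side in that gp120 library. Against a single wrong label run 75% of 8 genes at least 8-fold higher in gp120 that lay under the lowest gp120 library, such as Qpct (10.3 against 59.7 CPM or more), H60b (0.90 against 18.9), Gm6472 (22.8 against 49.3) and Gfap (1.79 against 5.34, and 14.9 against 85.3 in ependymal-like sums), and mt-Nd3 (144 CPM, at most 0.78 in gp120), but it is not excluded, since 5 of 10 genes that separate the genotypes lay on each side, Spp1 and C4b lay with gp120, mt-Nd3 was at most 0.43 in 3 of the other wt libraries, and the 2-month gp120 cord library, held out likewise, had 9 of 18 such genes on the wt side. A biological difference of this library was not tested, since no group of the design names one.

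Other splits of the libraries into groups of the same sizes were fitted in the same way. The real split alone reached its count for tissue (1 of 100 splits, 2773 genes against at most 888), genotype (1 of 100, 201 against 116) and 8 against 2 months (1 of 35, 271 against 1). For the counts of 0 between 2 and 4 and between 4 and 8 months the splits say nothing, since any split gives 0 or more (35 of 35, up to 25 and 20 genes). Within a tissue there are 10 splits, too few to exclude chance, and the real one alone reached its count (1 of 10) in cortex (491 against 0) and in cord (9 against 2). For tissue by genotype 5 of 100 splits, the real one included, gave 27 genes or more, up to 174, so that chance is not excluded. The same holds for genotype in T or NK cell-like sums, with 5 of 100. In the other classes the real tissue split was among 1 of 100 as large in astrocyte-, endothelial-, ependymal-, oligodendrocyte- and pericyte or smooth muscle-like sums, and 2 of 100 in T or NK cell- and border macrophage-like sums. The real genotype split was among 1 of 100 in border macrophage-, 2 of 100 in astrocyte-, ependymal- and pericyte or smooth muscle-, and 3 of 100 in endothelial- and oligodendrocyte-like sums. It was 1 of 32 in oligodendrocyte precursor-like and 1 of 10 in neuron-like sums, where 10 splits are too few to exclude chance.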

How the results depend on the processing

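Male cells alone in the library of both sexes, leaving out the 8-month wt cord and 4-month gp120 cortex libraries together, leaving out cluster 14, keeping clusters 11, 18 and 19, and leaving out libraries in the other classes were chosen after seeing the data. Of the values for single genes under other settings, 4453 kept their direction and side of the threshold, 318 no longer passed, 134 newly passed, 87 moved and 7 reversed. With 1 library left out 6848 kept both, 775 no longer passed, 85 newly passed, 198 moved and 0 reversed. Where no cause is named below, it was not tested.

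The 7 reversals were in sums over all cells passing the filter, which mix classes whose shares differ: Lsp1 (0.16), P2ry12 (0.49), Tmem119 (0.74) and Cx3cr1 (0.69) for genotype, Adamts1 (0.21) for 8 against 2 months and Lsp1 (0.12) for genotype in cortex, and in clusters 11, 18 and 19, Cenpe (0.74) for tissue by genotype.

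The following counts moved by over 1.5 times. For tissue (2773) it was 5767 over all cells, 864 with the marker gate and 1183 in clusters 11, 18 and 19. For genotype (201) it was 324 with DESeq2, 505 with no filter, 2332 over all cells and 324 in those clusters. For 8 against 2 months (271) it was 430 with DESeq2, 614 with no filter, 972 over all cells, 67 with the gate and 149 at 10% mitochondrial UMIs. For 4 against 2 months (0) it was 74 with DESeq2, 23 with voom, 158 with no filter, 18 over all cells, 37 with the gate, 25 in those clusters and 3 without both libraries. For 8 against 4 months (0) it was 171 with DESeq2, 160 with voom, 376 with no filter, 8 over all cells, 45 with the gate, 3 at 500 genes, 16 at 10% mitochondrial UMIs, 71 with equal cells, 8 with male cells, 195 in those clusters and 3 without both libraries. For genotype in cortex (491) it was 1222 with no filter, 269 at 10 CPM, 2820 over all cells, 145 with the gate, 1175 in the 6 cortex libraries alone, 300 with male cells, 247 in those clusters and 312 without both libraries. For genotype in cord (9) it was 64 with DESeq2, 3 with voom, 253 with no filter, 3 at 10 CPM, 20 at 500 genes, 15 at 10% mitochondrial UMIs, 33 with equal cells, 15 in the 6 cord libraries alone, 26 in those clusters and 35 without both libraries. For tissue by genotype (27) it was 99 with DESeq2, 0 with voom, 447 with no filter, 3 at 10 CPM, 0 over all cells, 1 with the gate, 11 at 500 genes, 17 at 10% mitochondrial UMIs, 14 with doublets kept, 6 with equal cells, 0 in those clusters and 9 without both libraries. For tissue by age (18) it was 66 with DESeq2, 507 with no filter, 7 at 10 CPM, 93 over all cells, 50 with the gate, 9 at 500 genes, 7 at 10% mitochondrial UMIs, 11 with equal cells, 8 with male cells, 9 without cluster 14, 81 in those clusters and 42 without both libraries. For genotype by age (0) it was 10 with DESeq2, 251 with no filter, 3 with the gate, and 1 each with equal cells, with male cells, in those clusters and without both libraries. With matched pairs as a block 2615 genes passed for tissue and 248 for genotype.

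In the other classes, a minimum of 10 CPM gave 105 for tissue and 50 for genotype in T or NK cell-like, 88 for genotype in neuron-like and 22 in oligodendrocyte precursor-like sums, and DESeq2 gave 24 for genotype in endothelial-like and 23 in neuron-like sums. Of the 34 tested lists, camera with an estimated correlation called 0 in each of the 8 comparisons, and fry called 16 for tissue, 0 for genotype, 4 against 2 and 8 against 4 months and genotype in cord, 3 for 8 against 2 months, 2 for genotype in cortex and 1 for tissue by genotype.

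With 1 library left out the counts ranged from 2193 to 3021 for tissue, 101 to 512 for genotype, 70 to 409 for 8 against 2 months, 0 to 25 for 4 against 2 months, 0 to 131 for 8 against 4 months, 130 to 749 for genotype in cortex, 5 to 27 in cord, 0 to 74 for tissue by genotype, 0 to 123 for tissue by age and 0 to 7 for genotype by age. In the other classes the tissue count ranged from 177 to 294 in astrocyte-, 88 to 187 in border macrophage-, 845 to 1227 in endothelial-, 988 to 1339 in ependymal-, 1781 to 2621 in oligodendrocyte-, 1230 to 1511 in pericyte or smooth muscle- and 5 to 38 in T or NK cell-like sums. The genotype count ranged from 4 to 25 in astrocyte-, 21 to 39 in border macrophage-, 21 to 98 in endothelial-, 17 to 40 in ependymal-, 9 to 158 in neuron-, 33 to 180 in oligodendrocyte-, 7 to 16 in oligodendrocyte precursor-, 45 to 285 in pericyte or smooth muscle- and 0 to 7 in T or NK cell-like sums. The 8-month wt cord library gave the highest genotype count when left out in microglia-, endothelial-, ependymal-, oligodendrocyte-, oligodendrocyte precursor- and pericyte or smooth muscle-like sums.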

Other observations

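The chromosome tests below were chosen after the results were seen. Some genotype differences recurred across cell classes. Hmgb1 was lower in gp120 in microglia-like sums (-0.92) and in ependymal-like (-1.05), oligodendrocyte precursor-like (-1.10) and oligodendrocyte-like sums (-1.21). Cwc22 was higher in gp120 ependymal-like (2.60) and oligodendrocyte precursor-like cells (3.88), and Rnase4, a ribonuclease gene, in astrocyte-like (2.76) and oligodendrocyte-like cells (2.62). Rnase4 overlaps Ang, which fell in gp120 microglia-like sums, on the same strand. The classes share libraries and free RNA, which moved the same way for Hmgb1 (134 CPM in wt and 61.5 in gp120) and Cwc22 (20.2 and 185). The prostaglandin synthase gene Ptgds was lower in gp120 oligodendrocyte-like cells (-1.13, adjusted p = 0.0286).

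Several of the genotype genes named in the report lie on chromosome 17: Ccr6, Qpct, Msh5, Rnaset2b, Lst1 and H2-K1. A hypothesis is that a segment of chromosome 17 that differs between the wt and gp120 mice adds to the genotype difference. Of 178 genes with the same direction in 6 of 6 pairs, 21 (11.8%) lay on chromosome 17, against 5.25% of the tested genes. With every chromosome tested alike by 10000 random draws, chromosome 14 also passed (14 of 379 tested genes, adjusted p = 0.037) beside chromosome 17 (21 of 578, adjusted p = 0.004). The 21 genes ran from position 6970634 to 87079155, and 11 of them lay in the span of the H2 genes (33938821 to 37483552). Without that span 6.0% of 167 genes lay on chromosome 17, against 4.32% of the tested genes (permutation p = 0.189). Without members of the interferon and antigen presentation lists, but with the span, it was 11.7% of 163 genes against 5.14% (permutation p = 0.0004). Of the 11 genes in the span, 6 carry no H2 name (Wdr46, Psmb9, Msh5, Ddah2, Lst1 and Gm7030). Outside the span the share did not pass the test, and within it a segment that differs cannot be told apart from a response of these genes to gp120. In the 2-month gp120 cord library Ccr6 (0.78 CPM against 0.48 in 2-month wt cord) and, in the span, Msh5 (5.18 against 4.35) stood near wt. Qpct (235 against 7.26) and, in the span, H2-D1 (2137 against 1202) were higher there. A segment not shared by all gp120 libraries could give such a mix, but these values come from 1 library and do not decide.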
